A study of Mus musculus with 4 samples.

How the data were processed

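Bulk RNA sequencing was made of adipocytes isolated from perigonadal white fat of CKO and control (WT) male littermates on a standard diet, with 2 libraries for each group. Per the labels' protocols, RNA was extracted with TRIzol and purified on RNeasy columns, and libraries were read on a NovaSeq 6000. Reads were aligned with STAR 2.7.5c to GRCm38.p6 and inspected with FastQC, per the submitters' processing notes. The counting tool, annotation and strand setting are not given in the sources used here. Each library carries a number of its own, and the labels say no more about whether the libraries came from separate animals, so p-values measure only the spread between these libraries. Replicate numbers follow the order of the records and pair no samples.

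The deposited table gives a symbol, a versioned Ensembl identifier and 4 columns for 55487 genes, and the authors describe its values as normalised counts on a log2 scale. In the deposited log2 values, 2 to the power of the value minus 1 was a whole number within 0.01 for 100% of genes in each library, with totals that differed between libraries. The values are therefore log2(reads + 1) without scaling between libraries. Of the identifiers, 55094 (99.3%) matched GENCODE M21 on GRCm38 with their version, and coordinates and overlapping genes are given from that match, 1-based. The symbols of 27 rows had been turned into 5-digit numbers, and 112 symbols stood on more than 1 row, for which the row of highest mean was used. Every column of values was used.

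Whole reads were recovered by rounding. Size factors (the median over 19847 genes of a library's reads over the gene's geometric mean) were 0.998 and 1.10 for CKO replicates 1 and 2 and 0.963 and 0.951 for WT replicates 1 and 2. Scaled reads plus a pseudocount of 1 were taken to log2, so fold changes of low genes are understated. Genes with a mean deposited log2 value of at least 3 were tested (16871 genes). Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided) on group alone, with Benjamini-Hochberg adjustment over the genes tested. There were 2 residual and 2.92 prior degrees of freedom, and the median change over all genes tested was 0.015. With 2 libraries against 2, the smallest two-sided p of an exact permutation test is 0.333, so single values were tested in limma alone. The design, made before the data were examined, foresaw limma on log2 values already normalised, or a count model should the table hold raw reads. The values met the second case, but as the deposited unit is log2, limma was kept and the count model was not run. The scaling step was added after the values had been seen.

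Before the data were examined, 36 gene lists were fixed for adipocyte functions, for inflammation and stress, and for other cell types the preparation could hold. Lists with at least 3 tested members (34) entered camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Estimated correlation, ranks and fry were alternatives. Members were also adjusted over the list alone. The genes named were set by a rule fixed at the same time. It names Prdm1, the 12 genes of largest change past the threshold in each direction or, where fewer than 5 pass, the 8 of smallest unadjusted p (leaving out unnamed gene models and pseudogenes), and up to 4 members of smallest p in each list. It adds Adipoq, Lep, Pparg, Adgre1, Cd68 and Lyz2. Lists called by camera, ranks or fry have 4 members named, and the others 1 or those that passed over the list alone. Genes chosen after their values were seen are so described. Some genes that the rule names are not reported here.

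The other settings planned were no filter, a minimum of 6, no trend, a robust fit, quantile normalisation, median centring, library weights, a further pseudocount of 10, and each library left out in turn. Unscaled values, scaling by total reads and voom weights were added after the data had been seen. No batch is named in the labels. Intervals of read ratios are exact binomial intervals at 95% and cover counting error only.

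The fit was tested on simulated reads for the comparison of CKO with WT, with 100 genes changed 2-fold and 100 changed 8-fold. With a within-group SD of 0.2 on the log2 scale (17316 genes), 81% and 100% of these were recovered and 8 unchanged genes were called. With each gene's SD as measured (17232 genes), 0% and 0% were recovered. Of 100 random lists of unchanged genes, 0 and 4 had a camera p under 0.05 in these simulations. Noise was drawn for each gene on its own, so these counts do not cover lists whose members move together. The measured SD, at the median over genes, was 0.23 between the CKO libraries and 0.39 between the WT libraries on the log2 scale.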

Results

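RNA sequencing was carried out on adipocytes isolated from perigonadal white fat, a visceral depot beside the reproductive organs, of male mice fed a standard diet. The groups were CKO mice and control littermates whose label reads WT, with 2 libraries each. The title of the series names BLIMP1, the transcriptional repressor encoded by Prdm1, and its role in macrophages in obesity and atherosclerosis; the labels leave the abbreviation CKO unexplained. The design implies 1 comparison, which asks how the adipocyte preparation of CKO mice differs from that of controls on the standard diet. Recovered read totals were 25260216 and 26742547 for CKO replicates 1 and 2, and 24152081 and 26145384 for WT replicates 1 and 2. A read was found for 25275 and 27547 genes in the CKO libraries and for 24246 and 24909 in the WT libraries. Differences are given as CKO minus WT on a log2(scaled reads + 1) scale.

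Macrophage transcripts were lower and transcripts of red blood cells and endothelium were higher in the CKO libraries, as gene lists, in calls lost with an estimated correlation between genes (adjusted p 0.783 each). The adipocyte identity list was also higher (median 1.35, adjusted p 0.783 with an estimated correlation), in a call lost without WT replicate 2 (median 0.32, adjusted p 0.277) and without CKO replicate 1 (0.0786). The lipid-associated macrophage list, which holds genes such as Trem2 and Gpnmb that mark macrophages in lipid-laden tissue, had a median log2 change of -3.58. The medians of the general macrophage list and the MHC class II list were -2.22 and -1.94, and that of the red blood cell list was 2.19. Of 34 gene lists tested, 16 changed, 9 upward and 7 downward, in limma's camera test with a preset correlation, and 0 with an estimated correlation (smallest adjusted p 0.783). No single gene passed the adjusted threshold.

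Prdm1 lies on chromosome 10 of GRCm38, from 44437177 to 44528501 on the minus strand. It had 152 and 386 reads in the CKO libraries and 514 and 1135 in the WT libraries. Scaled counts were 251 ± 140 in CKO and 864 ± 466 in WT (SD, n = 2). The log2 change was -1.79 (SE 0.59), with both CKO values below both WT values, and limma's adjusted p was 0.459. Its reads are given as a single count per library. Neither the part of the gene counted nor the part a CKO allele would lack is given in the sources used here. This level therefore does not check the labels. Xist was at 0 reads in all 4 libraries, and Ddx3y, a gene of the Y chromosome, had 1595 to 3213 reads.

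WT replicate 2 stood apart from the other libraries. The first principal component held 77.7% of the variance, and its scores were 84.4 and 38.0 for CKO replicates 1 and 2, -4.18 for WT replicate 1 and -118.2 for WT replicate 2. Pearson's r across genes was 0.975 between CKO replicate 2 and WT replicate 1, above the 0.969 between the CKO libraries and the 0.939 between the WT libraries. Adgre1, which encodes the macrophage surface protein F4/80, had 31880 reads in WT replicate 2, 8071 in WT replicate 1, and 3106 and 1384 in CKO replicates 2 and 1. Adipoq, which encodes the adipocyte hormone adiponectin, had 7561 reads in WT replicate 2 against 44425 in WT replicate 1, 43436 in CKO replicate 2 and 71437 in CKO replicate 1.

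Of 16871 genes tested, 0 were higher and 0 lower at an adjusted p under 0.05 in limma, and voom weights gave 0 as well. The smallest adjusted p was 0.459. At an unadjusted p under 0.05, 566 genes were higher and 1224 lower, where chance alone would give 844 in all on average. With the deposited values left unscaled, these counts were 859 and 855. Both CKO libraries lay above both WT libraries for 4031 genes (23.9%) and below them for 4519 (26.8%), against 16.7% each way by chance on average. Genes moved together along the first principal component, so the counts that chance gives can lie far from these averages. The other splits of the libraries into pairs gave 128 and 122 genes at an unadjusted p under 0.05 in limma. Without WT replicate 1, 797 genes were higher and 920 lower at the adjusted threshold, in a fit whose lone WT library is assumed to vary like the CKO libraries. No other left-out library gave a gene past the adjusted threshold.

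The genes of smallest unadjusted p that were lower in CKO did not pass the adjusted threshold, at an adjusted p of 0.459 each in limma. They were led by Dclk1, a doublecortin-like kinase on chromosome 3 (55242364 to 55539068), with scaled counts of 55.6 ± 14.9 in CKO and 381 ± 50.7 in WT (SD, n = 2) and a log2 change of -2.77 (SE 0.38). Tph2, the rate-limiting enzyme of serotonin synthesis in neurons, on chromosome 10 (115078641 to 115185022), had the largest difference of the 8 genes so named in this direction. It had 5 and 21 reads in the CKO libraries against 431 and 1506 in the WT libraries, a log2 change of -6.26 (SE 0.88). Trpc4, a cation channel, had 2 reads over the CKO libraries and 104 over the WT libraries, a WT to CKO ratio of 57.1 with a 95% counting interval of 15.4 to 478. The kinase gene Cdkl4, the G protein-coupled receptor gene Gpr50 and the matricellular protein gene Ccn5 had log2 changes of -4.44, -4.36 and -4.39. Eya4, a transcriptional coactivator, was at -3.56, and Olfml3, a secreted olfactomedin-like protein, at -2.16. Dclk1 and Cdkl4 overlap annotated genes on the opposite strand, and the counting's use of strand is not given in the sources used here.

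The genes of smallest unadjusted p that were higher in CKO did not pass either, with an adjusted p of 0.459 each in limma. Tbx3, a T-box transcription factor on chromosome 5 (119670669 to 119684724), led them with scaled counts of 4306 ± 676 in CKO and 766 ± 335 in WT (SD, n = 2), a log2 change of 2.55 (SE 0.38). Tbx3, Dbp, Slc39a8 and Baiap3 overlap annotated genes on the opposite strand. Dbp, a transcription factor under control of the circadian clock, differed little between replicates, with 712 ± 27.4 in CKO and 289 ± 15.9 in WT (SD, n = 2), a log2 change of 1.30. Slc39a8, a zinc and manganese transporter, had 391 ± 5.12 and 144 ± 4.23 (SD, n = 2), a log2 change of 1.43. Trim10 had 92 reads over the CKO libraries and 2 over the WT libraries, a WT to CKO ratio of 0.0239 with a 95% counting interval of 0.00285 to 0.0887. Tdo2, which breaks down tryptophan, and Baiap3 were 3.15 and 2.79 higher. H2-Q7, a nonclassical MHC class I gene, was 1.72 higher, and near-identical neighbours can share its reads.

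**Figure D1:**
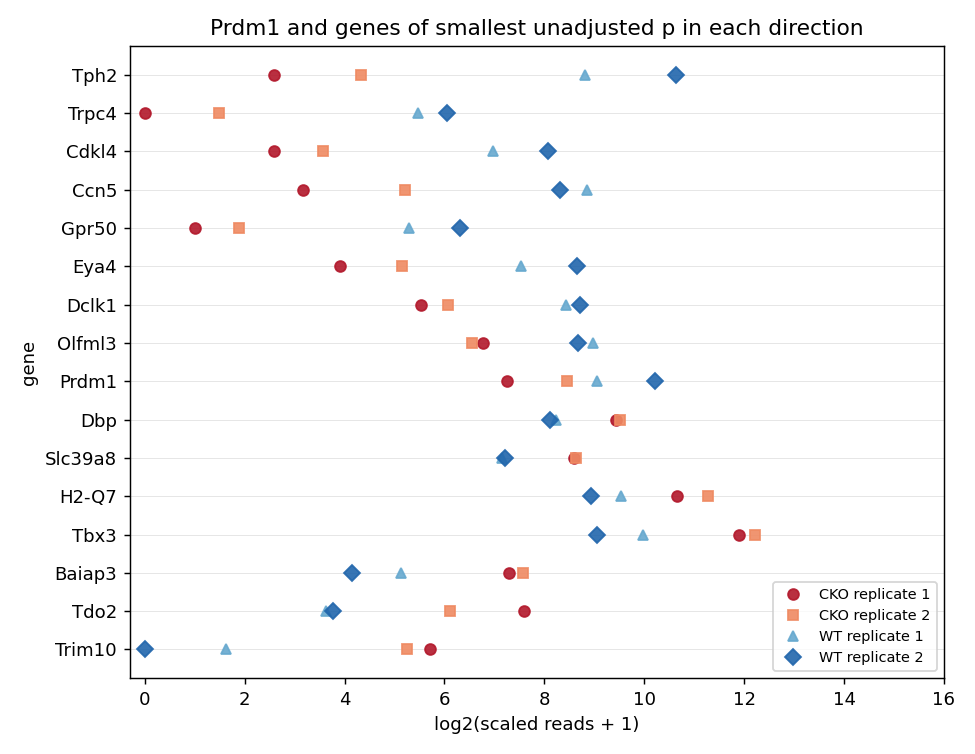
Each point is 1 library's log2(scaled reads + 1) on the horizontal axis, for Prdm1 and 15 genes of smallest unadjusted p on the vertical axis, ordered by log2 change, with circles and squares for CKO replicates 1 and 2 and triangles and diamonds for WT replicates 1 and 2. Every gene has both CKO points on the same side of both WT points, from Tph2 (log2 change -6.26) to Trim10 (4.67), and none passed limma's adjusted threshold.

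Macrophage genes were lower in CKO in nearly every case. Of 23 macrophage genes tested, 20 had a negative log2 change, and 14 fell at an adjusted p under 0.05 when adjusted over the list alone, against 0 over all genes tested. The log2 changes of Adgre1, of Cd68, a lysosomal glycoprotein of macrophages, of Itgam and of Cd14 were -3.08 (SE 0.76), -3.22 (SE 0.86), -2.67 and -2.22, each with an adjusted p of 0.0421 over the list alone (limma). Lyz2, the myeloid lysozyme gene, had a log2 change of -2.39 (SE 0.94) that did not pass. Of 13 lipid-associated macrophage genes, 13 were lower and 10 fell when adjusted over the list alone. These included the macrophage metalloelastase gene Mmp12 (-4.59), the proton pump subunit gene Atp6v0d2 (-4.39), Trem2 (-3.89) and Lipa, the lysosomal acid lipase (-2.75), each with an adjusted p of 0.0405. The call of both lists had an adjusted p of 4.3e-07 in camera and 0.783 with an estimated correlation. Of the lipid-associated macrophage genes, 3 also stand in another list. Without WT replicate 2 the macrophage median was -1.37, with 10 members past the list's threshold, and the lipid-associated median was -2.66 with 0. Without CKO replicate 1 the medians were -1.93 and -2.06, with 0 members past it in either list, and without CKO replicate 2 the members past it were 0 and 9.

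The MHC class II, cell cycle, lysosomal, inflammatory and cholesterol synthesis lists were also lower in CKO in camera, and each of these 5 calls was lost with an estimated correlation (adjusted p 0.783). All 7 MHC class II genes were lower and 6 fell when adjusted over the list alone, among them H2-DMb1 (-2.26), H2-Aa (-1.97), H2-DMa (-1.94) and H2-Eb1 (-1.90; camera adjusted p 3.7e-05 for the list, 0.783 with an estimated correlation). All 12 cell cycle genes were lower, with a list median of -2.71 (camera adjusted p 1.4e-06, 0.783 with an estimated correlation) and 0 past the threshold over the list alone; the log2 changes of Birc5, Top2a, Cdk1 and Cdca8 were -3.36, -3.09, -2.75 and -2.60. Of 25 inflammatory cytokine and NF-kB genes, 22 were lower (median -1.01, camera adjusted p 4.4e-06, 0.783 with an estimated correlation), with 0 over the list alone. The log2 changes of Tnf, Cxcl2, Nlrp3 and the acute-phase gene Saa3 were -2.90, -2.61, -2.29 and -1.91. Of 18 autophagy and lysosome genes, 16 were lower (median -0.96, camera adjusted p 7.4e-05, 0.783 with an estimated correlation), with 0 over the list alone; Ctsd, Ctsz, Hexa and Npc2 were at -2.20, -2.15, -2.14 and -0.99. Of 20 cholesterol synthesis and uptake genes, 16 were lower (median -0.51, camera adjusted p 0.00433, 0.783 with an estimated correlation), with 0 over the list alone. Dhcr7, which makes cholesterol from its last precursor, Msmo1 and Mvd were at -1.36, -1.24 and -1.01. The adjusted p of cholesterol synthesis was 0.0693 with the preset correlation when CKO replicate 2 was left out. Each of these lists was highest in WT replicate 2, the library with the most Adgre1 reads. Without it the cell cycle, inflammatory and lysosomal medians were -1.50, -0.58 and -0.52. The 6 MHC class II genes became 0 without CKO replicate 1, CKO replicate 2 or WT replicate 2.

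**Figure D2:**
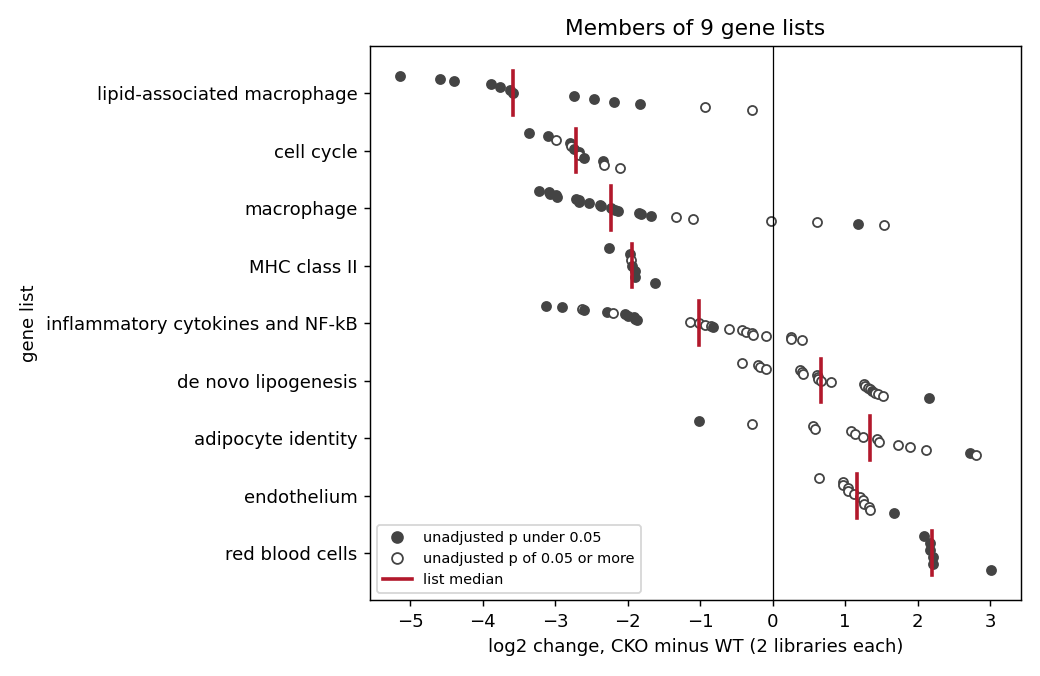
Each point is a gene's log2 change (CKO minus WT, 2 libraries each) on the horizontal axis, by gene list on the vertical axis; filled points had an unadjusted p under 0.05 in limma, and the red bars are list medians. All 13 lipid-associated macrophage genes lie left of 0 around a median of -3.58, and all 6 red blood cell genes lie right of 0 around 2.19.

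The red blood cell, endothelial and interferon response lists were higher in CKO in camera, with 6 of 6, 12 of 12 and 23 of 27 genes higher, and these calls were lost with an estimated correlation (adjusted p 0.783 each). All 6 red blood cell genes rose when adjusted over the list alone, with Hba-a2 up by 2.22, Hbb-bt by 2.21 and Hba-a1 by 2.17 (camera adjusted p 5.8e-06 for the list, 0.783 with an estimated correlation). The haemoglobin genes have near-identical copies that can share reads. All 12 endothelial genes were higher (median 1.16, camera adjusted p 7.4e-05, 0.783 with an estimated correlation), with 0 over the list alone; the log2 change of Kdr, which encodes a VEGF receptor, was 1.68 (SE 0.61), and those of Emcn, Tie1 and Tek were 1.32, 1.25 and 1.12. Of 27 interferon response genes, 23 were higher (median 0.64, camera adjusted p 5.5e-04, 0.783 with an estimated correlation), with 0 over the list alone. Iigp1, Ifit2 and Irf7 were at 1.52, 1.25 and 0.95. The adjusted p of the interferon list was 0.0640 with the preset correlation when CKO replicate 2 was left out. Without WT replicate 2, in which all 3 lists were lowest, the medians were 1.42 for red blood cells, 0.44 for endothelium and 0.22 for the interferon response. The endothelial median was 1.90 without WT replicate 1, and the interferon median was 0.98 without WT replicate 1 and 0.41 without CKO replicate 2. Red blood cell genes past the list's threshold were 5 without CKO replicate 1 and 0 without CKO replicate 2.

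Adipocyte and lipid metabolism genes were higher in CKO as lists, in calls that rested on WT replicate 2 and CKO replicate 1. They were lost with an estimated correlation, at an adjusted p of 0.800 for de novo lipogenesis and 0.783 for the other 4 lists. Of 14 adipocyte identity genes, 12 were higher (median 1.35, camera adjusted p 0.00952, 0.783 with an estimated correlation). The glyceroneogenic enzyme gene Pck1 and Cfd, which encodes adipsin, were at 2.72 (SE 1.05) and 2.80 (SE 1.46), and Slc2a4, the insulin-responsive glucose transporter, at 1.90, while Cebpb was at -1.01. Adipoq was at 1.47 (SE 0.97) and Pparg, the master regulator of adipocyte differentiation, at 0.58 (SE 0.39). All 11 triglyceride synthesis genes were higher (median 0.77, camera adjusted p 0.0109, 0.783 with an estimated correlation), Mogat1 by 2.28, Gpat3 by 2.03, Dgat1 by 1.16 and Gpat4 by 0.62. Of 21 de novo lipogenesis genes, 17 were higher (median 0.66, camera adjusted p 0.00681, 0.800 with an estimated correlation), with Acacb at 2.15, Mlxipl at 1.45, Acaca at 1.41 and Fads2 at 1.38. Of 17 lipolysis and lipid droplet genes, 14 were higher (median 1.08, camera adjusted p 0.0360, 0.783 with an estimated correlation). Aqp7 and G0s2 were at 1.66 and 1.52, while Plin2, a lipid droplet coat protein also made by other cells, was at -1.72 and Hilpda at -2.15. Of 17 insulin signalling and glucose use genes, 14 were higher (median 0.62, camera adjusted p 0.0103, 0.783 with an estimated correlation), with Irs1 at 1.78 and Foxo1 at 1.05, and with Ptpn1, a phosphatase that damps insulin signalling, at -1.14. No member of these 5 lists passed when adjusted over its list alone. Both CKO libraries lay above both WT libraries for 5 of 14 adipocyte identity, 1 of 11 triglyceride and 2 of 21 de novo lipogenesis genes. For lipolysis and insulin genes it was 4 of 17 and 7 of 17. As medians of each gene's distance from its mean over the 4 libraries, CKO replicate 2 was at 0.22, 0.040, 0.13, 0.17 and 0.14 for these lists in turn. WT replicate 1 was at 0.28, 0.39, 0.34, 0.33 and 0.090, higher for all but the insulin list. Of the adipocyte identity, lipolysis and insulin genes, 11, 5 and 2 also stand in another list, so these calls share genes in part.

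Without WT replicate 2, the adjusted p of the adipocyte identity, insulin, de novo lipogenesis, triglyceride and lipolysis lists was 0.277, 0.591, 0.586, 0.721 and 0.857, with medians of 0.32, 0.25, 0.11, 0.13 and 0.24. Without CKO replicate 1 it was 0.0786, 0.0555, 0.0805, 0.134 and 0.134, so each of these calls was lost in either case. Without WT replicate 1 the medians were 2.36, 1.32, 1.46, 1.66 and 2.02. The insulin and de novo lipogenesis medians were 1.01 and 1.13 without CKO replicate 2, and the triglyceride median was 0.46 without CKO replicate 1. Of 49 oxidative phosphorylation genes, 42 were higher by a small amount (median 0.23, camera adjusted p 0.0109, 0.811 with an estimated correlation), with 0 over the list alone. Ndufs3, Ndufb10 and Ndufa5 were at 0.54, 0.44 and 0.43 and Atp5g1 was at -0.61. That list's adjusted p was 0.940 without CKO replicate 1 (median 0.0056) and 0.0540 without WT replicate 1. Its median was 0.45 without CKO replicate 2 and 0.15 without WT replicate 2. The macrophage, lipid-associated macrophage, MHC class II, cell cycle, inflammatory, lysosomal, endothelial and red blood cell lists kept their call, with the preset correlation, without each library in turn.

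**Figure D3:**
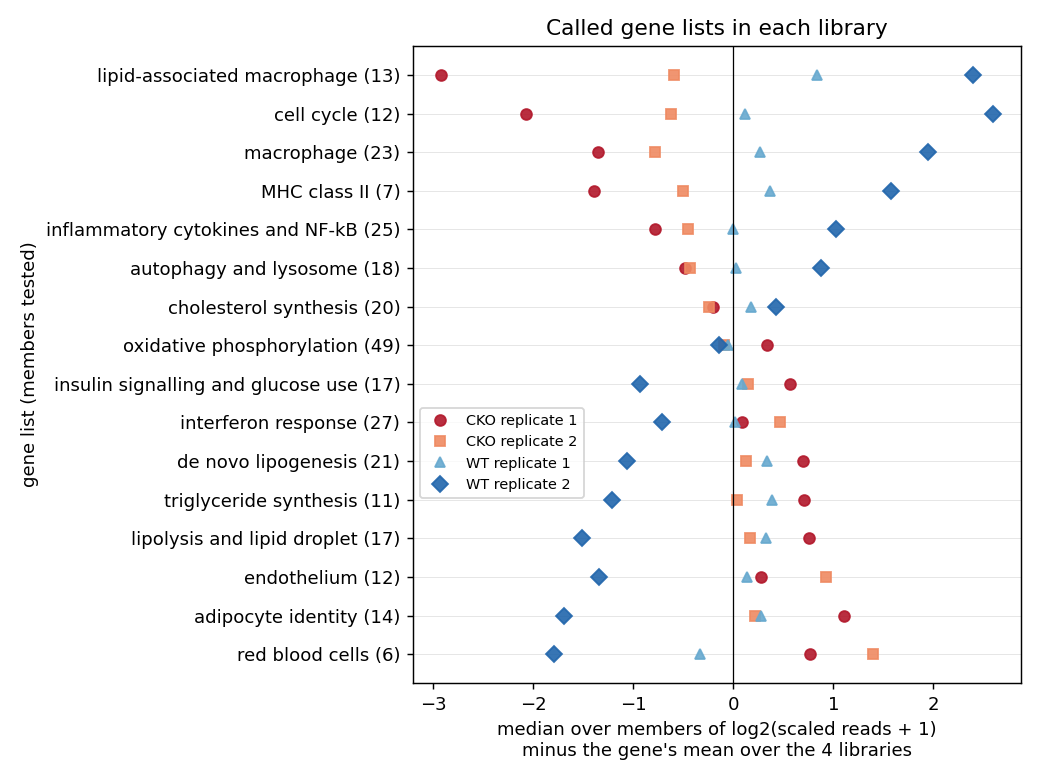
Each point is 1 library's median over a list's members of log2(scaled reads + 1) minus the gene's mean over the 4 libraries, on the horizontal axis, for the 16 called lists on the vertical axis with the number of members tested; symbols mark the libraries as named in the key. Within the lipid-associated macrophage list WT replicate 2 is the highest of the 4 libraries (2.40), and within adipocyte identity it is the lowest (-1.70), where WT replicate 1 (0.28) and CKO replicate 2 (0.22) lie side by side.

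Genes of the circadian clock were mostly higher in CKO and did not pass camera in the main setting. Of 17 tested, 12 were higher (median 0.57, camera adjusted p 0.0708, 0.783 with an estimated correlation), and 0 passed over the list alone. At an unadjusted p under 0.05 in limma, 5 were higher and 3 lower. The clock output gene Dbp and the repressor genes Nr1d1 and Nr1d2 were at 1.30, 2.23 and 0.84, and Bhlhe40 at -1.08. The list was the only call of limma's fry test, which asks whether a list's genes move on balance in a single direction, at an adjusted p of 0.0403, and camera called it without WT replicate 2 (median 0.44, adjusted p 0.0121, against 0.0869 to 0.186 without each other library). The time of day at which tissue was taken is not given in the sources used here.

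The other lists did not pass camera with the 4 libraries in the main setting, and some passed with a library left out or in another setting. Smooth muscle and pericyte genes had a median of 0.84 (adjusted p 0.0551), with Rgs5, Notch3, Myh11 and Des at 1.28, 1.29, 1.11 and 0.84, and passed with ranks (0.0439). Their median was 0.29 (adjusted p 0.352) without WT replicate 2 and 0.74 (0.398) without CKO replicate 2, while they passed without CKO replicate 1 (1.07, 0.00280) and without WT replicate 1 (1.38, 0.00270). Skeletal muscle genes had a median of 1.09 with Mylpf at 1.09, and fatty acid oxidation genes of 0.32 with Cpt1a at -0.93, both at an adjusted p of 0.0708. The skeletal muscle median was 0.44 (adjusted p 0.352) without WT replicate 2, 1.80 (0.0550) without WT replicate 1 and 0.74 (0.225) without CKO replicate 2, and the list passed without CKO replicate 1 (1.42, 0.0225). The fatty acid oxidation median was 0.045 (0.779) without WT replicate 2 and 0.17 (0.474) without CKO replicate 1, and the list passed without CKO replicate 2 (0.52, 0.0240) and without WT replicate 1 (0.55, 0.0150). Extracellular matrix genes had a median of -0.29 (0.104) with Col1a1 at -1.74. They passed without WT replicate 2 (median -0.55, adjusted p 2.3e-04) and without CKO replicate 2 (-0.39, 0.0227), while the median was -0.058 (0.839) without WT replicate 1 and -0.10 (0.587) without CKO replicate 1. Mast cell genes had a median of 0.67 (0.147) with Kit at 1.20. It was 0.028 (0.455) without CKO replicate 1, 0.43 (0.358) without WT replicate 2, 1.25 (0.161) without WT replicate 1 and 0.99 (0.0480) without CKO replicate 2. ER stress genes had a median of -0.21 (0.153) with Sdf2l1 at -2.15, and of -0.34 (0.0912) without WT replicate 2 and -0.11 (0.294) without WT replicate 1. Adipokines had a median of 0.81 (0.165), of 1.64 (0.00379) without WT replicate 1 and of 0.013 (0.358) without WT replicate 2, and Lep, the leptin gene, was at -1.23 (SE 0.61). Dissociation and immediate early genes had a median of 0.17 (0.381) with Socs3 at 0.72. It was 0.46 (0.00408) without CKO replicate 1, 0.31 (0.0967) without WT replicate 2, -0.037 (0.702) without CKO replicate 2 and -0.050 (0.839) without WT replicate 1. Of the dissociation genes, Hspa1a and Hspa1b had 10700 and 12204 reads in CKO replicate 2 and 471 to 1261 in the other libraries, and the cause was not tested. The sex-linked genes had a median of 0.19 (0.438) with Ddx3y at 0.40. Among 5 neutrophil genes (median -0.94, adjusted p 0.529), S100a9 rose by 2.21 and S100a8 fell by 1.79, each with an adjusted p of 0.0256 over the list alone. S100a9 had few reads, 51 and 54 in CKO and 13 and 7 in WT, and the neutrophil genes Ly6g and Cxcr2 had 0 to 5 in every library. The neutrophil median was -0.14 (0.740) without CKO replicate 2 and -0.15 (0.779) without WT replicate 2. Fibroblast and preadipocyte genes had a median of 0.0085 and a mean of -0.06, with a negative camera direction (0.695). Of these, Lum and Mfap5 fell by 1.90 and 1.96, with an adjusted p of 0.0494 over the list alone. These calls over the neutrophil and fibroblast lists were all lost without CKO replicate 1, CKO replicate 2 or WT replicate 2. Medians were -0.13 for T and NK cells with Trac at -2.27, -0.13 for fatty acid uptake with Lrp1 at -1.40, -0.19 for mitochondrial genome transcripts with mt-Nd3 at -0.35, 0.73 for B and plasma cells with Cd22 at -3.58, and 0.20 for mesothelium with Lrrn4 at 2.44, all at 0.695. Lrrn4 had 110 and 66 reads in CKO replicates 1 and 2 and 52 and 3 in WT replicates 1 and 2. Thermogenesis genes had a median of 0.20 (0.843) with Gk at -1.12. Too few members passed the filter to test epididymis (0 genes) and testis germ cells (2 genes), where Prm2 had 93 reads in CKO replicate 1 and 1 to 10 in the other libraries.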

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

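Unscaled values, scaling by total reads and voom were chosen only after the values were seen. The count of genes past the adjusted threshold stayed at 0 in both directions in all settings that used the 4 libraries. With a library left out it ranged from 0 to 797 genes higher and 0 to 920 lower, the upper values without WT replicate 1. At an unadjusted p under 0.05, 566 genes were higher in the main setting, 993 without a filter, 333 with the stricter filter and 859 with unscaled values. With a library left out, 83 to 2849 were higher and 212 to 2899 lower. Unscaled values moved the median change of all genes from 0.015 to 0.147, and the share of higher genes among those at an unadjusted p under 0.05 from 31.6% to 50.1%, since the size factors, which were larger for both CKO libraries than for both WT libraries, were then left out. Prdm1 was lower in every setting, by -2.38 to -1.20 with a library left out and with an adjusted p of 0.0617 to 1.00. For the 124 named genes the sign was kept in 1339 of 1343 pairs of gene and setting that used the 4 libraries. The others were of Cd36, at -0.0065 in the main setting, 0.33 with quantile normalisation, 0.029 with median centring, 0.13 unscaled and 0.078 with total scaling. With a library left out it ranged from -0.13 to 0.10, and Lpl from -0.78 to 0.21.

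The number of lists called was 15 to 20 in settings with 4 libraries and the preset correlation, 17 with ranks, 1 with fry and 0 with an estimated correlation, which allows for members moving together. It was 13 to 18 with a library left out, and 8 of the 16 called lists kept their call in each such case. The lipolysis list lost its call with unscaled values (adjusted p 0.0784) and with total scaling (0.0811). Lists outside the 16 gained a call with the stricter filter (smooth muscle 0.00939, neutrophils 0.0334, fatty acid oxidation 0.0456, circadian clock 0.0456), without a filter (extracellular matrix 0.0341), with quantile normalisation (fatty acid oxidation 0.0417) and with library weights (smooth muscle 0.0285). Lists that turned direction in camera or fry had not been called, and the cause was not tested. The thermogenesis list turned without a filter (median -0.45) and, in the direction given by the test while the median stayed positive, with quantile normalisation (0.13), with unscaled values (0.33) and in fry (0.20). The neutrophil list turned together with its median without a filter (0.60), and the B and plasma cell list with the stricter filter (-0.91). With a library left out, medians ranged from -0.88 to 0.62 for thermogenesis, -0.028 to 1.22 for B and plasma cells, -0.65 to 0.28 for T and NK cells, -0.049 to 0.25 for mesothelium, -0.31 to 0.057 for fatty acid uptake, -0.23 to 0.14 for fibroblasts and preadipocytes, -0.050 to 0.46 for dissociation genes, -0.56 to 0.18 for mitochondrial transcripts, 0.013 to 1.64 for adipokines and -0.057 to 0.36 for sex-linked genes. Ddx3y ranged from -0.023 to 0.80. No paired analysis was possible because the labels give no number or litter that ties a CKO library to a WT library.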

Other observations

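The tests of macrophage RNA and of Prdm1 and the count over other splits were chosen only after the results were seen, whereas the test around the Prdm1 locus was set out beforehand. The genes of this and the next paragraph were chosen after their values were seen. Soat1, which esterifies cholesterol, had 325 and 1844 reads in CKO replicates 1 and 2 and 4143 and 13197 in WT replicates 1 and 2, a log2 change of -3.39 (SE 0.95). Nceh1, which hydrolyses cholesterol esters, and the protease gene Ctsk were at -3.23 and -3.33. Gpnmb had the largest change of its list, -5.15 (SE 1.65), with 418 and 11359 reads against 34370 and 144383. Of other macrophage genes, Folr2 and Mrc1 were at -1.82 (SE 0.65) and -1.68 (SE 0.59). Lyve1, which lymphatic vessels also express, was at 1.18 (SE 0.41), Cd209f at 1.77 (SE 0.54), Timd4 at 1.54 (SE 0.89) and Cd163 at 0.62 (SE 0.52). None of these genes passed limma's adjusted threshold.

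Among the most abundant transcripts, some varied widely between libraries of the same group and others did not. Car3, a carbonic anhydrase abundant in fat, took 3.38% and 1.98% of reads in CKO replicates 1 and 2, and 1.79% and 0.382% in WT replicates 1 and 2. Cfd took 2.02% and 0.666% in CKO and 0.524% and 0.0471% in WT. Fabp4 took 1.67% and 1.82% in CKO and 1.22% and 0.461% in WT, Cd36 0.627% and 0.737% against 0.620% and 0.669%, and Lpl 0.886% and 0.470% against 0.751% and 0.726%. Cyp2e1 had 162825 and 38519 reads in CKO and 24875 and 1258 in WT, and the angiotensinogen gene Agt 14822 and 4876 against 2805 and 384. The lysosomal protease gene Ctsb took 1.43% of reads in WT replicate 2 and 0.180% in CKO replicate 1. H2-Q5 and H2-Q6, near-identical neighbours of H2-Q7, were 1.61 and 1.72 higher in CKO, and the 3 genes are not independent observations where they share reads.

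A first pattern is the lower level of macrophage lists in CKO. A lower share of adipocytes in the WT libraries, if it raised all other cell types alike, would leave endothelial genes lower in CKO too. Their median was higher in CKO, by 0.089 (CKO replicate 1 against WT replicate 1) to 2.21 over the 4 pairs of a CKO and a WT library. The endothelial median exceeded the macrophage median by 1.71 at the least and 4.96 at the most over these pairs. This argues against an equal rise of all other cell types. It does not speak against fewer adipocytes together with an unequal rise of other cells. A candidate explanation that remains open is that the libraries hold different amounts of the same macrophage population over a shared background, and macrophage numbers in the tissue and carry-over in isolation were not tested. A comparison of each gene's share of the rise from CKO replicate 1 to WT replicate 2 does not decide it. List medians differed by 0.0353 between the CKO replicates and 0.0018 between CKO replicate 2 and WT replicate 1. Permutation p-values across genes, which are not independent, were 0.0281 and 0.898. The first difference was small yet had a p under 0.05, which met neither the outcome set for the explanation nor that against it. The comparison also used only genes with more scaled reads in WT replicate 2 than in CKO replicate 1. These were 20 of 23 macrophage genes and 12 of 13 lipid-associated genes, so it says nothing of Lyve1, Timd4 and Cd163. Scaled reads of Lyve1, Timd4 and Cd163 were 209, 16.8 and 1176 in WT replicate 2, below the 670, 162 and 1740 in CKO replicate 1. In CKO replicate 2 they were 345, 34.4 and 871, and in WT replicate 1 they were 214, 37.4 and 549. Of these genes only Lyve1 was higher in both CKO libraries than in both WT libraries, while Folr2 and Mrc1 were lower. A larger amount of the same population would not by itself lower Lyve1. Lymphatic vessels also express Lyve1, and it was chosen after its values were seen, so it does not decide the question either.

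A second pattern is the lower level of Prdm1. If it only followed macrophage RNA, its shares of the same rise should lie among those of the 20 macrophage genes used there. Between CKO replicate 2 and WT replicate 1 its share was 0.177, within the quartiles of those genes (0.150 and 0.192). Between the CKO replicates it was 0.190, above the upper quartile (0.0901) and below the highest member (0.238), so the values do not decide whether less macrophage RNA may account for it. Per 1000 Adgre1 reads there were 110 and 124 Prdm1 reads in CKO replicates 1 and 2, and 63.7 and 35.6 in WT replicates 1 and 2. The log2 change of Adgre1 (-3.08) was larger than the macrophage list's median (-2.22), while that of Mrc1 (-1.68) was smaller than Prdm1's (-1.79). As the list's median fell further than Prdm1, such a ratio is on average higher in CKO over most genes of the list. It turns over genes that fell less. Of these, Mrc1 had a change that differed from Prdm1's by less than the SE of either (0.59 each).

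The last pattern is the number of genes at an unadjusted p under 0.05. Differences inherited with the Prdm1 locus would gather around it on chromosome 10, but 9 of 89 other genes tested within 10 Mb (10.1%) were at that level against 10.6% elsewhere, an odds ratio of 0.947 (95% interval 0.417 to 1.89, Fisher's exact p = 1). Which stretch of chromosome 10 differs between the groups is not given in the sources used here. As the interval also reaches 1.89, such differences are not excluded. Of the 3 splits of the 4 libraries into pairs, 1, the real split, gave 1790 such genes, and the highest of the others gave 128. With 3 splits no share under 0.05 can be reached. The genotype itself remains an untested explanation.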
